A study of Homo sapiens with 24 samples.

How the data were processed

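Gene expression was measured in SH-SY5Y, a human neuroblastoma cell line used as a model of neuronal differentiation, on 24 Illumina arrays. The labels place the arrays in 8 groups of 3, by retinoic acid (RA) treatment, by day 2 or day 4, and by the manipulation of the microRNA miR-125b. The sample titles distinguish a scrambled control (SCR), OE, read here as overexpression, knockdown (KD) and both together (OE+KD). No label spells OE out, and the source names write DP in its place, which is not explained in the sources used here, so every OE value rests on the title's label. Total RNA was extracted with Trizol and RNeasy columns and labelled with biotin, per the labels' protocols. The growth protocol in the labels describes other cells and other reagents than those of the sample titles, so the dose of RA, the delivery of the reagents and the separation of the cultures are not given in the sources used here. P-values therefore measure only the spread between the 3 arrays of each group, which may be technical.

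The deposited scanner table holds 1 linear intensity per probe and array for 20589 probes. Between 14.3% and 17.6% of the values on each array were negative, so a background had been subtracted before deposit. The array version, the scanner software and detection p-values are not given in the sources used here. A separate table holds intensity values normalized by the authors, with the method not given in the sources used here. Compared with the scanner values, each array in it followed a smooth curve against the first array (the scrambled control without RA, day 2, replicate 1). The SD of the steps along that curve was 0.0001 to 0.0005 on the log2 scale. Values under 20 stood at 20, which held for 37.8% to 40.1% of the values on each array, and the medians were 47.3 to 53.2. The other deposited table gives log2 fold changes in 5 columns, log2 per the file headers.

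For the main values the scanner intensities were corrected with normexp (offset 50), quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. The offset compresses fold changes of dim probes. A probe was tested when it lay above the median of its array on all 3 arrays of at least 1 group, which kept 10691 probes, or 51.9%. One linear model with a mean for each of the 8 groups was fitted to all 24 arrays (lmFit, eBayes, 16 residual degrees of freedom), so all groups shared 1 estimate of the spread. The p-values were adjusted by the Benjamini-Hochberg method over the probes tested in each comparison, and a probe was called at an adjusted p under 0.05. Every adjusted p of a probe is limma's. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

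The comparisons, tests and alternatives were fixed before the data were examined, except where stated. The probes carry Illumina IDs that the tables used here do not pair with genes. For that reason 19 gene lists, a test for miR-125b seed sites and a choice of 1 probe per gene were not run, no gene is named, and every probe was tested on its own. The level of miR-125b was not analysed here, so the labels OE and KD were not checked against it. The rule for naming took, for each comparison, the 10 called probes with the largest rise and the 10 with the largest fall whose replicates did not overlap between the groups. At most the first 2 of each are printed. Without gene names, biology was followed through sets of probes, a choice made after the data were examined. Each set was defined by calls in 1 comparison or pair of comparisons and read in another that shared no array with it. The 14 set tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, each adjusted over the family of 14. An OE score was the mean normalized log2 intensity of the OE-higher set minus that of the OE-lower set, compared between groups by exact permutation.

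The procedure was tested on simulated data. In the simulation of OE against scrambled without RA on day 2, with 20589 probes of which 10345 were tested and 200 were changed, 82.5% of changes of 0.5 log2 and 100% of changes of 1 log2 were called. In that simulation 8 of 186 calls were false, or 4.3%. Its noise was independent between arrays, with 1 SD per probe, and probes changed in 1 group only. The real arrays deviated together by replicate number, as given below, so the share of false calls among the real ones may differ. No pair of arrays held identical values. For comparisons that share arrays, correlations and covariances were simulated 20 times for unchanged groups.

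Replicate numbers come from the sample titles. Arrays of the same number in different groups deviated together (mean r across probes 0.242 over 84 pairs). Every same-number correlation was over 0.1 in 7 of the 9 comparisons of 2 groups, the exceptions being OE+KD against scrambled (lowest 0.098) and RA against no RA in OE arrays (lowest 0.007). The main model has no block, and the model with the replicate number as a block was an alternative. The others were no background correction, median scaling, cyclic loess, the authors' normalized intensities, no filter, a stricter filter (above the 60th percentile of all 24 arrays), array weights, a trended robust variance, a fit to the compared groups alone, an adjusted p under 0.01, a fold change of at least 1.5, and leaving out each array in turn. No slide was given, so no slide block was fitted.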

Results

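Expression profiles were collected from SH-SY5Y neuroblastoma cells labelled OE, read here as overexpression, or KD, knockdown, of miR-125b, a microRNA studied here for its part in neuronal differentiation, with the level of miR-125b not analysed here. Without RA there were scrambled control and OE arrays on day 2 and on day 4. With RA there were scrambled control, KD, OE and OE+KD arrays on day 2. Each of these 8 groups had 3 arrays. Mean scanner intensity per array ran from 617.8 to 1134.2, with a median of 809.8. Replicates correlated with r of 0.978 to 0.997 across the tested probes, with a median of 0.995. The number of arrays limits the precision of every value. Residual SD per array ran from 0.074 to 0.225 log2, highest on replicate 2 of the OE group with RA.

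**Figure D1:**
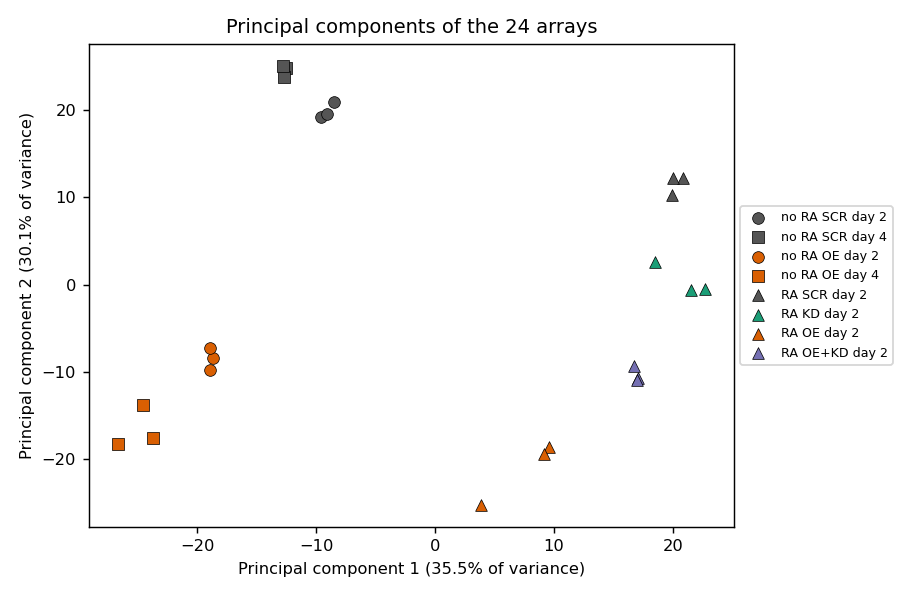
Each point is 1 of the 24 arrays, placed by its first principal component (x axis, 35.5% of variance) and its second (y axis, 30.1% of variance), computed on normalized log2 intensities of the tested probes. Colour gives the manipulation of miR-125b and shape the RA treatment and day, and replicate 2 of the OE group with RA lies apart from the other 2 arrays of its group, at 3.84 on the x axis and -25.2 on the y axis.

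The first question was how the transcripts of OE cells differed from those of scrambled control cells without RA. On day 2, OE raised 1668 probes and lowered 1691 of the 10691 tested. ILMN_6588 rose most, by 2.63 log2 (SE 0.086, a 6.20-fold change, limma adjusted p = 3.33e-17), from 11.60 ± 0.04 to 14.23 ± 0.05 (SD, n = 3 per group). ILMN_13364 rose by 2.02 log2. ILMN_21370 fell by 2.23 on the log2 scale (SE 0.087, limma adjusted p = 1.03e-15), and ILMN_5708 fell by 1.76. Most changes were small: 53 probes rose and 95 fell at least 2-fold, and the median size among called probes was 0.41 log2. Among the tested probes, 5424 (50.7%) had replicates that did not overlap between the groups, against 10% by chance. With median scaling the share of called probes that were higher was 36.1% in place of 49.7%. Without background correction ILMN_13364 rose by 4.33 log2, and by 3.56 in the authors' normalized intensities, since its level in the control arrays (6.50 ± 0.04, SD, n = 3) lay near the low end.

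By day 4 the OE cells differed from their day 4 controls at more probes, 2801 higher and 2706 lower. ILMN_13364 rose by 4.55 log2 (SE 0.111, a 23.4-fold change, limma adjusted p = 1.26e-20) and ILMN_6588 by 4.06 log2 (SE 0.086, limma adjusted p = 8.46e-22). Without background correction ILMN_13364 rose by 6.74 log2, and by 6.59 in the authors' normalized intensities, since its level in the day 4 control arrays (6.60 ± 0.10, SD, n = 3) lay near the low end. ILMN_21370 fell by 2.43 on the log2 scale and ILMN_21261 fell by 2.20. At least 2-fold, 150 probes rose and 221 fell. The effects of the 2 days correlated with r = 0.718 across probes, which are not independent replicates, and these comparisons share no array. Of the 2551 probes called on both days, 97.5% changed in the same direction, with 1226 higher on both days (437.0 if the lists were independent) and 1261 lower on both (428.0). With median scaling 68.9% of the called probes were higher in place of 50.9%, and the median of all probes moved to 0.13 log2.

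The OE effect itself differed between the days at 1380 probes (limma, adjusted p under 0.05 for the difference). At 712 of them the change kept its direction and was larger on day 4, at 80 it was smaller, and at 588 it had opposite signs on the 2 days, which the choice of probes by a large difference favours. Of the 1380 probes, 1009 were not called between the days in scrambled arrays, where 12.3% of all tested probes were called. The OE effect on day 4 and the change between days in scrambled arrays share the day 4 controls. The covariance of these 2 effects was -0.0271 against -0.00599 simulated for unchanged groups, so part of the difference between the days may lie in the controls. ILMN_13364 rose by 2.53 log2 more on day 4 than on day 2 (SE 0.157, limma adjusted p = 8.80e-11) and ILMN_6588 by 1.43 more (SE 0.122). The difference at ILMN_21370 was -0.20 log2 (limma adjusted p = 0.294). Across all tested probes the SD of the OE effect was 0.33 log2 on day 2 and 0.45 on day 4. The count was 2278 with median scaling, 762 with a stricter filter on dim probes and 2409 with array weights. Median scaling shifted the median difference of all probes by 0.20 log2 and turned the share of positive differences from 45.6% to 82.6%, so the direction of small differences is relative to the scaling.

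In the scrambled cultures without RA, 619 probes were higher and 696 lower on day 4 than on day 2, and 5 rose and 7 fell at least 2-fold. ILMN_25878 rose by 1.18 log2 (SE 0.127) and ILMN_23892 by 1.17. ILMN_8120 fell by 1.57 on the log2 scale (SE 0.095, limma adjusted p = 4.07e-11) and ILMN_5188 fell by 1.45. With median scaling 30.4% of called probes were higher in place of 47.1%. The count was 3243 with array weights and 2263 when only these 2 groups were fitted.

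RA, a differentiating agent for neuroblastoma cells, gave the largest single changes among the 9 comparisons of 2 groups. In scrambled control cells on day 2, ILMN_28662 rose by 7.66 log2 (SE 0.123, a 201.8-fold change, limma adjusted p = 4.38e-25), from 6.40 ± 0.23 to 14.06 ± 0.05 (SD, n = 3 per group). ILMN_27300 rose by 7.05 log2, or 132.9-fold. ILMN_3487 fell by 3.31 on the log2 scale (SE 0.108, limma adjusted p = 2.48e-18) and ILMN_23892 fell by 2.40. In all, 995 probes were higher and 1078 lower, 89 and 57 of them at least 2-fold. Both rising probes lay near the low end without RA, so the size of their folds depends on the background correction: without it ILMN_28662 rose by 12.61 log2 and ILMN_27300 by 14.27. With median scaling 28.1% of called probes were higher in place of 48.0%, the count was 1328 with a stricter filter on dim probes, and it was 3739 with array weights.

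In OE cells RA raised 1204 probes and lowered 1238. Of these, 650 were also raised and 669 also lowered in scrambled cells, where independent lists would share 112.1 and 124.8. The effects of RA in scrambled and in OE cells, which share no array, correlated with r = 0.834 across probes, and 99.5% of the 1325 probes called in both had the same direction. ILMN_28662 rose by 5.66 log2 (SE 0.123, 50.4-fold) and ILMN_27300 by 5.55 (46.8-fold). ILMN_3487 fell by 2.44 on the log2 scale and ILMN_23892 fell by 2.24. The count was 1581 with a stricter filter on dim probes and 1078 when only these 2 groups were fitted. Without background correction ILMN_28662 rose by 8.52 log2 and ILMN_27300 by 10.97.

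**Figure D2:**
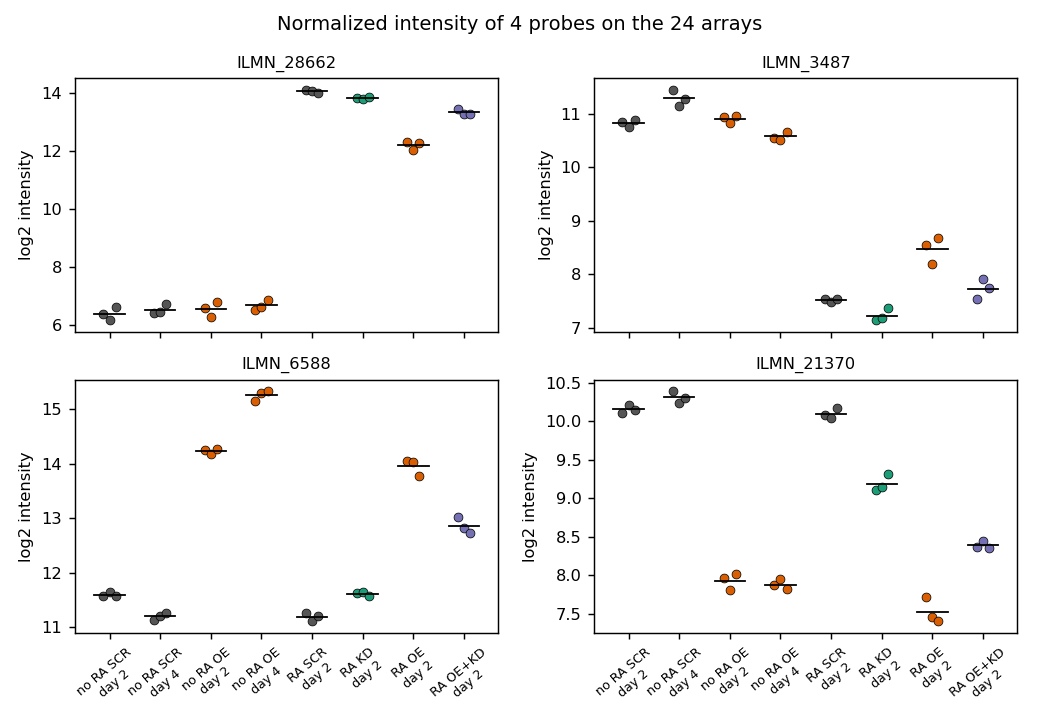
Normalized log2 intensity (y axes) of 4 probes on each array, by group (x axes), with points for single arrays and a line at the mean of each group of 3. ILMN_28662 and ILMN_3487 separate the RA groups from the others, and ILMN_6588 and ILMN_21370 separate the OE groups from the scrambled controls, with OE+KD between OE and scrambled.

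OE in RA-treated cells raised 2119 probes and lowered 2123. ILMN_6588 rose by 2.77 log2 (SE 0.086, limma adjusted p = 9.83e-18) and ILMN_22953 by 2.13. ILMN_21370 fell by 2.57 on the log2 scale (SE 0.087, limma adjusted p = 3.19e-17) and ILMN_9057 fell by 2.09. At least 2-fold, 87 probes rose and 118 fell. The OE effects with and without RA on day 2, which share no array, correlated with r = 0.857 across probes, and 99.6% of the 2632 probes called in both had the same direction. Of the 1226 probes raised by OE on both days without RA, 1026 were also called higher with RA, and of the 1261 lowered, 1099 were called lower. Independent lists would give 86.6 and 85.0 probes called in all 3 OE comparisons. The median change of the raised set was 0.45 log2 and that of the lowered set -0.51 (camera adjusted p = 6.45e-12 and 2.93e-10 with an estimated correlation). The count was 2681 when only these 2 groups were fitted.

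A difference of the OE effect with and without RA was called at 79 probes, 50 of them positive and 29 negative. With RA, OE lowered the 2 probes with the largest RA responses: ILMN_28662 fell by 1.84 on the log2 scale (SE 0.123, limma adjusted p = 1.81e-11) and ILMN_27300 fell by 1.45 (SE 0.094). Without RA both lay near the low end in scrambled and OE arrays, so an OE effect on them could not be measured there. Of the 40 probes called for this difference and for RA, in the same direction, in both scrambled and OE cells, 22 had a smaller RA effect in OE cells. With RA, ILMN_28662 stood at 14.06 ± 0.05 in scrambled arrays, 12.22 ± 0.15 in OE arrays and 13.34 ± 0.10 in OE+KD arrays (SD, n = 3 each). This count moved with most settings, between 26 without background correction and 156 with array weights, and it lay between 34 and 48 when any 1 array of the scrambled groups on day 2 or of OE without RA on day 2 was left out. It was 122 with the replicate number as a block, and 63.3% of the differences were positive against 77.3% with median scaling and 84.6% without background correction.

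KD in RA-treated cells changed fewer probes than OE did, 921 higher and 823 lower. ILMN_16098 rose by 2.09 log2 (SE 0.122, limma adjusted p = 1.31e-11), from 9.12 ± 0.09 to 11.21 ± 0.17 (SD, n = 3 per group), and ILMN_12713 by 1.80. ILMN_20030 fell by 1.23 on the log2 scale (SE 0.099, limma adjusted p = 1.76e-09) and ILMN_24484 fell by 1.15. In all, 40 rose and 8 fell at least 2-fold. The count was 2960 with array weights.

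Probes that OE raised were, on balance, also raised by KD. In arrays that took no part in choosing the sets, the probes raised by OE without RA had a median change of 0.19 log2 in KD against scrambled, with 422 called higher and 25 lower, and the lowered probes a median of -0.11, with 60 called higher and 271 lower (camera adjusted p = 2.80e-09 and 0.000615 with an estimated correlation). KD with RA and OE without RA on day 2 share no array, and their effects correlated with r = 0.439 across probes, with 88.7% of the 996 probes called in both changing in the same direction. KD and OE with RA share the scrambled arrays. Their covariance was 0.0439 against 0.00606 simulated for unchanged groups, with r of 0.484 against 0.503 simulated. ILMN_21370, lowered by OE, stood at 10.10 ± 0.06 in scrambled, 9.19 ± 0.11 in KD and 7.53 ± 0.17 in OE arrays with RA (SD, n = 3 each). ILMN_5708, also lowered by OE, lay on the other side of scrambled with KD, at 10.66 ± 0.11 in scrambled, 10.95 ± 0.15 in KD and 8.77 ± 0.07 in OE arrays, with KD minus scrambled of 0.29 log2 (limma adjusted p = 0.0527). Sets responsive to RA in OE arrays were not called in KD, with medians of 0.01 log2 for the raised and 0.03 for the lowered probes (camera adjusted p = 0.280 and 0.255). Without KD replicate 3 the first of these medians was 0.04 and was called with the preset correlation. The estimated correlation was not used without that array, and with all arrays it gave a camera adjusted p of 0.602 for this set. Medians near 0 do not mean that KD left these probes unchanged. Of the 1204 raised probes KD called 175 higher and 117 lower, where independent lists would share 104 and 93. Of the 1238 lowered probes it called 139 higher and 105 lower, against 107 and 95.

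In OE+KD cells the OE-responsive probes lay nearer to their scrambled level than in OE cells. OE+KD against OE gave 980 probes higher and 902 lower, with 7 and 1 at least 2-fold. ILMN_5708, lowered by OE, rose by 1.35 log2 (SE 0.103, limma adjusted p = 1.25e-08), and ILMN_9057 by 1.15. ILMN_6588, raised by OE, fell by 1.09 on the log2 scale (SE 0.086, limma adjusted p = 1.29e-08), and ILMN_5930 fell by 0.99. ILMN_5930 was not called for OE with RA (0.12 log2, limma adjusted p = 0.686). In OE+KD it lay further from scrambled, at -0.87 log2 (limma adjusted p = 0.00372). Without replicate 2 of OE its change against OE was -0.70 log2. Probes raised by OE without RA had a median change of -0.14 log2 (297 called lower, 16 higher) and the lowered ones 0.19 (468 called higher, 20 lower; camera adjusted p = 3.24e-07 and 1.03e-06 with an estimated correlation). Across probes the effect correlated with that of OE without RA on day 2, with which it shares no array, at r = -0.424. The count moved with single arrays: it was 962 without replicate 2 of OE, 1171 without replicate 1 of OE+KD, and 104 when only these 2 groups were fitted, where ILMN_5930 was not called. With median scaling 22.8% of called probes were higher in place of 52.1%, and in the authors' normalized intensities 63.9%.

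OE+KD cells still differed from scrambled control cells, with 1508 probes higher and 1603 lower. ILMN_22953 rose by 1.85 log2 (SE 0.125) and ILMN_6588 by 1.68. ILMN_21370 fell by 1.71 on the log2 scale (SE 0.087, limma adjusted p = 5.35e-13) and ILMN_8101 fell by 1.31. The probes raised by OE without RA had a median change of 0.32 log2 and the lowered ones -0.33 (camera adjusted p = 2.68e-11 and 7.99e-09 with an estimated correlation). With median scaling 29.6% of called probes were higher in place of 48.5%.

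The OE score placed the 4 RA groups in order. It was -0.63 ± 0.01 in scrambled, -0.28 ± 0.03 in KD, 0.08 ± 0.01 in OE+KD and 0.43 ± 0.04 in OE arrays (SD, n = 3 each). KD thus lay 33.5% and OE+KD 66.9% of the way from scrambled to OE. The differences were 0.36 for KD minus scrambled, 1.06 for OE minus scrambled, 0.71 for OE+KD minus scrambled, -0.35 for OE+KD minus OE and 0.36 for OE+KD minus KD. In each of these 5 comparisons the groups did not overlap and the 2-sided exact permutation p was 0.1, before and after adjustment over the 5, the smallest that 3 arrays against 3 can give.

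**Figure D3:**
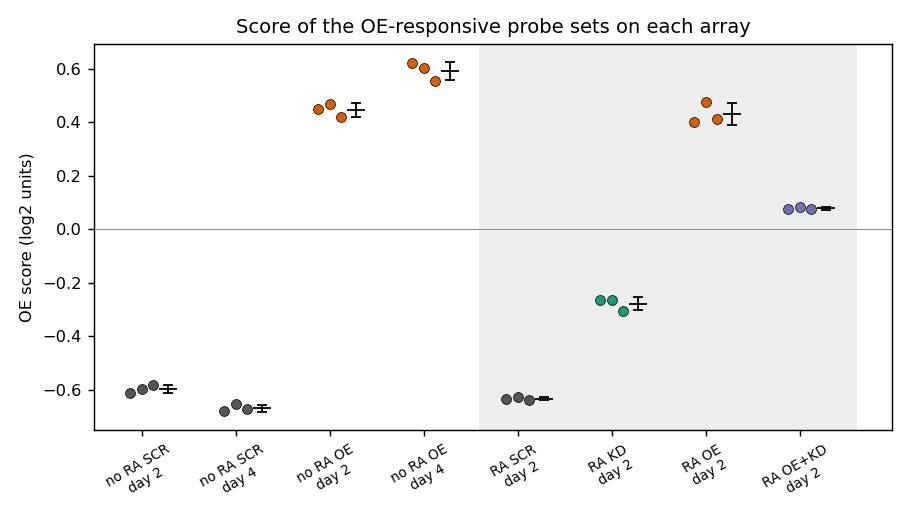
OE score in log2 units (y axis) of each array by group (x axis), with points for arrays and a bar for mean and SD (n = 3). The sets were chosen on the 4 groups without RA, and in the shaded RA groups the means ran from -0.63 in scrambled to 0.43 in OE.

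**Figure D4:**
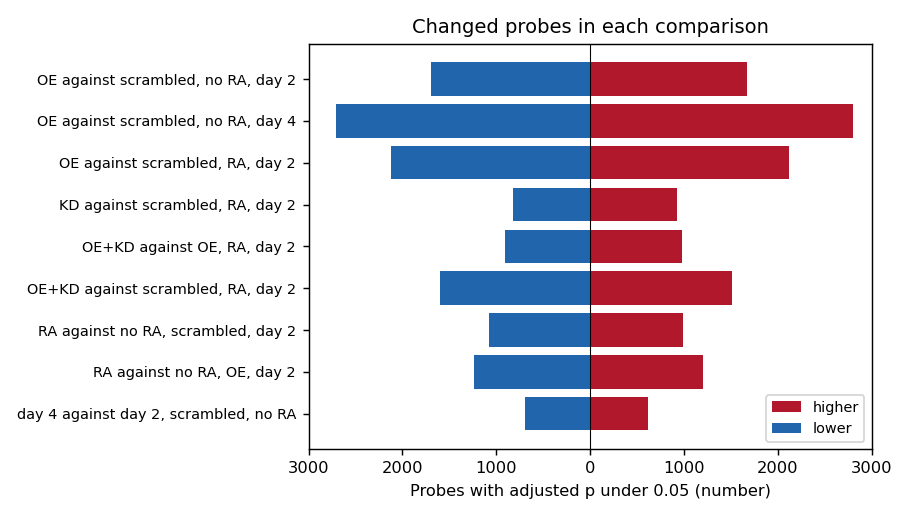
Number of probes called higher (right, red) and lower (left, blue) in each comparison of 2 groups, at a limma adjusted p under 0.05 of 10691 probes tested. The counts run from 619 higher and 696 lower between days in scrambled cells to 2801 and 2706 for OE on day 4.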

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

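In this part the tests of the KD pattern, the test of handling shared by replicate number, the permutation within replicate numbers, the test on a curve over intensity, the tests on the SD over all probes and the comparison of the KD effect with and without OE were chosen after the results were seen.

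In 3 cases a difference of an effect between groups passed the test of the difference itself. The OE effect differed with and without RA at 79 probes. It differed between day 4 and day 2 at 1380 probes. The KD effect differed with and without OE, both with RA, at 1420 probes, 1140 of them with opposite signs of the KD effect, which the choice of probes by a large difference favours. That last count was 891 with median scaling, which turned the share of positive differences from 48.2% to 33.7%, and 776 when only its own 4 groups were fitted. Permuting the residuals of the additive model over the 12 arrays 100 times, the real arrangement included, gave as many probes in 2 arrangements for the 79 (highest other 132), in 2 for the 1380 (highest other 1694) and in 1 for the 1420 (highest other 397). That permutation did not keep arrays of a replicate number together, although such arrays deviated together. Permuting only among the 4 arrays of each replicate number, 100 times with the real arrangement included, gave as many probes in the real arrangement alone (1 of 100) for each, with highest others of 0, 118 and 582. With the replicate number also as a block in the model, the real counts were 122, 1989 and 2044 and the highest others 3, 306 and 1402, again with 1 of 100 as large. The share of arrangements with as many probes was thus under 0.05 in each. The permutation within replicate numbers was chosen after the first was seen, and the separation of the cultures is not given. Chance differences between cultures are therefore not excluded. What gave the high counts of single arrangements, up to 1694 over the 12 arrays, was not tested. The permuted residuals still held the real difference, so an arrangement near the real one can give a high count.

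For the 9 comparisons of 2 groups the 10 splits of 6 arrays are too few for a share under 0.05. The real split alone (1 of 10) gave as many probes in each. The real counts were 3359 and 5507 for OE without RA on day 2 and day 4, 4242 for OE with RA, 1744 for KD, 3111 for OE+KD against scrambled, 2073 and 2442 for RA in scrambled and OE cells and 1315 between days, with 0 as the highest other in each. For OE+KD against OE the real count was 1882 and the highest other 55. The splits that part as many pairs of replicate numbers are among these, and so gave no more.

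KD, the opposite manipulation where OE is read as overexpression, moved the OE-responsive probes in the direction of OE. Noise of the shared scrambled arrays is argued against by r = 0.439 between effects that share no array (SD 0.026 over replicate numbers), and 1 outlying array by a median of the OE-higher probes that stayed at 0.185 log2 or more without any 1 array. In OE+KD against OE, which holds no scrambled array, the OE-lower probes lay 0.206 log2 above the others. The delivery of the reagents is not given, so the dose of OE may differ between these groups. This change therefore cannot decide whether KD had an effect. It also runs away from OE and was measured with OE present. It thus cannot decide whether KD without OE moved these probes or the scrambled arrays alone were shifted. An effect of the scrambled control itself beside a KD effect stays open, since the KD score lies 0.356 above the scrambled score and each of the 8 groups is labelled as scrambled, OE, KD or OE+KD, with no group free of all of these. A response of RA-treated cells to either change of miR-125b also stays open as a hypothesis, with the level of miR-125b not analysed here.

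Replicate 2 of the OE group with RA stood apart from its group, with a residual SD of 0.225 log2. A smooth intensity trend is argued against by the 1.70% of the variance of its median-scaled deviation that lay on a curve over intensity (up to 15.9% on other arrays), whereas its residual SD after cyclic loess, 1.01 times that after quantile normalization, decides nothing about scanner bias, since both remove such a trend. A stronger or weaker OE response, as the main part of its deviation over all probes, is argued against by the correlation of that deviation with the OE effect without RA, r = 0.0216. Its OE score was the highest of its group, 0.4765 against 0.3995 and 0.4125, so a slightly stronger response of the OE sets is not excluded. Handling shared by arrays numbered 2 cannot be told apart from the array's own deviation: the 7 correlations with the deviations of the other replicates 2 had a mean of 0.284, from -0.082 to 0.708, the highest with OE without RA on day 4. An RA score, the probes raised by RA in scrambled cells minus those lowered, was the lowest of its group, 0.1468 against 0.2516 and 0.2886. With the RA sets of OE cells, whose choice used this array, the score was the highest, 0.5714 against 0.3656 and 0.3877. A different response to RA is thus not excluded and was not tested. No other biological explanation was tested, and the labels give replicates no property of their own.

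Whether the OE effect was larger on day 4 depended on the measure. Over the probes called on day 2, the measure chosen beforehand, the ratio of median absolute effects (day 4 over day 2) was 1.07, and 1.08 without replicate 2 of OE on day 4. Under other scalings it ran from 0.961 with median scaling to 1.10 with cyclic loess, so scaling may account for this small excess. Over the probes called on either day the ratio was 1.56, with 1.52 without that array and 1.59 to 1.82 under other scalings. The larger number of calls on day 4 favours day 4 in this choice of probes. The ratio of SDs over all tested probes was added after these values were seen, because probes picked on day 2 favour day 2. It was 1.38, 1.37 without that array, and at least 1.40 under each other scaling, which argues against both explanations for the spread over all probes. A growth of the OE effect with time is one hypothesis that stays open, and a difference in culture between the days was not tested.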

How the results depend on the processing

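The probe sets and the KD effect with and without OE were added after the data were examined, and the other settings were fixed before. Of the recomputed values of named probes and sets, 477 under other settings and 431 without 1 array kept their side of the threshold, and no called value changed its direction, while medians near 0 of sets that were not called did change sign under some settings. The exceptions were ILMN_5930 in OE+KD against OE, not called at -0.99 log2 when only these 2 groups were fitted, and the RA-raised set of OE arrays read in KD, called at a median of 0.04 without KD replicate 3. The named probes were picked for the largest changes of each comparison, and the sets were defined anew under each setting. Their stability therefore says little about the other called probes. The stricter filter did not test ILMN_13364, ILMN_20030, ILMN_21261, ILMN_21370, ILMN_22953, ILMN_23892, ILMN_24484, ILMN_25878, ILMN_27300, ILMN_28662, ILMN_3487 and ILMN_5930. Values of these probes were recomputed under 9 other settings in place of 10, so their calls under that filter are not known. Every call of a set in this part is from camera with the preset correlation. Signal over background limits the dim probes, whose folds depend on the offset. Choosing 1 probe per gene, the gene lists, the seed sites and a slide block were not run, and the cause of the moves below was not tested unless stated.

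With median scaling the count for OE by day was 2278 and for KD by OE 891. The difference of the OE effect with and without RA (79) was 26 without background correction, 44 with median scaling, 49 in the authors' normalized intensities, 41 without a filter, 37 with the stricter filter, 156 with array weights, 32 at an adjusted p under 0.01 and 35 in its own groups. The stricter filter, which tests fewer probes, gave 1328 for RA in scrambled cells, 1581 for RA in OE cells and 762 for OE by day. Array weights gave 2960 for KD, 3739 for RA in scrambled cells, 3243 between days and 2409 for OE by day. Fits to the compared groups alone gave 2681 for OE with RA, 104 for OE+KD against OE, 1078 for RA in OE cells, 2263 between days and 776 for KD by OE. Without a filter the correlation of KD with OE without RA on day 2 was 0.401.

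By construction stricter thresholds call fewer probes. An adjusted p under 0.01 gave 2221 for OE on day 2 without RA, 1013 for KD, 809 for OE+KD against OE, 1861 for OE+KD against scrambled, 1275 and 1398 for RA in scrambled and OE cells, 692 between days, 597 for OE by day and 705 for KD by OE. A fold change of at least 1.5 with an adjusted p under 0.05 gave, in the same order with OE on day 4 and OE with RA after OE on day 2, 800, 1738, 1086, 323, 210, 545, 525, 542, 138, 581 and 649.

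With the replicate block the OE effect with and without RA gave 122 probes, and no other count moved by over 1.5 times. In the comparisons where not every same-number correlation was over 0.1 the replicate block gave 3714 for OE+KD against scrambled (3111 without) and 3117 for RA in OE cells (2442 without). Leaving out 1 array gave 34 to 99 for the OE effect with and without RA and 962 to 2674 for OE+KD against OE, the lowest without OE replicate 2 and the highest without OE replicate 1.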

Other observations

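The probe sets and the readings of the authors' fold table in this part were chosen after the data were examined.

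Sets of probes responsive to RA in scrambled cells were not called as sets under OE on day 4 without RA. The probes that RA raised in scrambled cells had a median change of 0.02 log2 in OE cells on day 4 without RA, and those it lowered -0.04 (camera adjusted p = 0.884 and 0.282), with 285 of the 995 raised probes called higher by OE and 276 lower. Of the 1078 lowered probes 300 were called higher and 380 lower (fry adjusted p = 0.0583). With median scaling the second median was 0.12 and the median of all probes 0.13, so its change of sign followed the shift of all probes. Across probes the RA effect in scrambled cells and the OE effect on day 4, which share no array, correlated at r = 0.0298. The RA effect in OE cells, which also shares no array with the OE effect on day 4, correlated with it at r = 0.129. Of the 1454 probes called in both, 64.3% had the same direction. Higher in both were 472 and lower in both 463, where independent lists would share 315 and 313, and 286 and 233 had opposite directions. Although no array is shared, OE arrays with RA and OE arrays on day 4 deviated together by replicate number. Their deviations correlated at r = 0.708 for replicate 2 and 0.451 for replicate 1. How far this raised the correlation of the 2 effects was not tested. The probes higher on day 4 in scrambled cells had a median change of -0.13 log2 with RA in OE cells, called with a preset correlation (camera adjusted p = 0.00018) and not with an estimated one (adjusted p = 0.0524).

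Several probes moved the same way under both manipulations of miR-125b. ILMN_16098, the largest rise with KD, changed by 2.09 log2 with KD, 1.01 with OE and 1.20 with OE+KD, each against scrambled with RA (SE 0.122, limma adjusted p = 1.31e-11, 3.57e-07 and 6.37e-08). ILMN_12713 changed by 1.80, 1.97 and 1.61 log2 (SE 0.081). Not every probe did so. ILMN_20030, the largest fall with KD, changed by -1.23 log2 with KD and by 0.505 with OE, each against scrambled with RA (SE 0.099, limma adjusted p = 1.76e-09 and 0.000236). Adding KD to OE changed ILMN_16098 by 0.20 log2 (limma adjusted p = 0.269). On the OE score, OE raised RA-treated cells by 1.06 without KD and by 0.36 with KD.

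The authors' deposited table of fold changes does not match all of its headers. A regression of each column on their normalized intensities over 10547 probes left residuals of at most 5.54e-10 and so gave the arrays used. In the authors' deposited table both columns without RA subtract the mean of 6 scrambled arrays, those of day 2 and day 4 together. The 3 columns with RA use 2 of the 3 treated arrays, replicates 1 and 2. The columns headed as KD and as OE and KD against scrambled without RA subtract the scrambled arrays with RA: their correlation across probes with the difference from the header groups was 0.594 and 0.630, and with the difference from the RA controls 0.967 and 0.977. At a log2 change of at least 1 or at most -1 the authors' deposited table lists 182 and 273 probes for OE on day 2, 353 and 619 for OE on day 4, 355 and 367 for OE with RA, 104 and 82 for KD and 128 and 138 for OE with KD.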
